A study of Mus musculus with 24 samples.

How the data were processed

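Gene expression was measured by bulk RNA sequencing in 24 libraries of mouse T cells made in culture. Th1, Th17, regulatory (Treg) and activated CD8 T cells were each treated with the vehicle DMSO or with 1 of 5 kappa opioid receptor (KOR) agonists, named here WMS-200, WMS-64, WMS-75, WMS-76 and WMS-83. Per the labels the dose was 0.1 µM for up to 5 days, the RNA was column-purified total RNA, and the libraries were enriched for poly(A) RNA. Each combination of cell type and treatment has 1 library. The deposited values are raw read counts per gene, which the authors made with fastp, HISAT2 and featureCounts per the submitters' processing notes. The versions of these tools, the strand setting, the genome build and the annotation release are not given in the sources used here, so coordinates are printed as the file gives them. All 24 value columns were matched to a labelled sample, with 0 columns left over. The titles give the compounds longer suffixes that run on from one cell type to the next, while the protocol lists 5 compounds, and the column names carry 5 codes in every cell type; these codes were used. One title reads Th17 with WMS-83 although its source name, characteristics and column are those of Th1, and it was taken as Th1. The column names call the CD8 libraries Tc1, while their titles call them CD8+ T cells. In the column names each library also carries a WT number that the labels do not explain. The number is 4 in all Th1 libraries and 2 in all CD8 libraries. Among the Th17 libraries it is 2 for DMSO, 3 for WMS-83 and 1 for the other 4. In Treg it is 3 for DMSO and WMS-200 and 2 for the other 4.

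Genes with too few reads were removed with edgeR's filterByExpr by cell type at a minimum count of 10, which left 15885 of 56748 genes, 12567 of them protein coding. The values used as normalised expression are CPM, counts scaled to a common library size by TMM. A quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with robust dispersion, was fitted to all libraries, and p was adjusted over all genes tested by the method of Benjamini and Hochberg, with a threshold of 0.05. The first model had a term per cell type and per compound (15 residual degrees of freedom). It gave each cell type against the mean of the other 3, the 5 agonists together and each compound against DMSO across the cell types, every pair of compounds, and an F-test among the 5 agonists. The second model had agonist or DMSO within each cell type (16 residual degrees of freedom) and gave the agonists against DMSO inside each cell type and the test of whether that effect differs between cell types. Inside a cell type the 5 agonists were taken as replicates of one another and DMSO had 1 library, so the lone DMSO library was assumed to vary like the other groups. A compound against DMSO in 1 cell type has no replicate and was not tested by itself. The alternative with the WT number as a block leaves such a comparison in Treg, WMS-200 against DMSO. The biological coefficient of variation was 0.133 in the first model and 0.127 in the second. Errors of log2 fold changes are standard errors from the model, SDs are between the 6 libraries of a cell type or the 5 agonist libraries, and intervals are at 95%. Log2 CPM for the choice of named genes had a prior count of 2.

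Gene lists of known function were written before the data were examined, as were the comparisons, the models, the named-gene rule and the alternatives, apart from those named as added. The lists cover the Th1, Th17, Treg, CD8 cytotoxic, CD4 lineage and Th2 programs, and opioid receptors and peptides. Signalling lists cover G protein and cAMP signalling, immediate early genes, cytokines and chemokines, inhibitory receptors, naive and memory markers, proliferation and the interferon response. Metabolic and stress lists cover glycolysis, hypoxia, oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, lysosome, the integrated stress and unfolded protein response, heat shock, the p53 response and apoptosis. Markers of B, myeloid, NK and gamma delta, erythroid and stromal cells and sex-linked transcripts complete the lists. In the glycolysis list Aldoa has 2 identifiers in the file and counts as 2 members. Of these, 29 lists had enough measured members for a test, and the erythroid list, with 1, was counted but not tested. Each list was tested against the other genes with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and by itself with fry, and p was adjusted over the lists of a comparison.

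The rule for named genes took genes with a symbol and a mean log2 CPM of at least 1. For a cell type it took the members of the lineage lists and the 6 largest rises among called genes whose 6 libraries all lie above every other library. For the agonists across cell types it took the 10 largest rises and falls with 1 direction in all 4 cell types, and 5 of each for a compound. Within a cell type it took the 8 largest rises and falls whose 5 agonist libraries all lie on 1 side of DMSO. The F-test and the test between cell types gave the 10 smallest p. From each list came up to 4 members with the largest change, and where nothing passed the 5 smallest p were taken as values without a call. Opioid genes and the markers of other cell types were always included. Genes named outside the rule are said to have been chosen after their values were seen.

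Each sample holds between 15188284 and 21946887 counted reads. A count of 0 allows up to 3 counts, given in CPM on the same scale as the other values, and such limits cover counting error only, because reads copied by PCR are not independent molecules. Pairs of libraries of 1 cell type were checked for duplicates: over the 60 pairs the chi-square per degree of freedom between counts was at least 3.97. Each kind of comparison was tested on simulated data made from these libraries with log2 changes of 0.5, 1 and 2 added. For the agonists across cell types 79.1, 95.5 and 100% of these were recovered, with 10 false calls of 193. For a single compound 49.3, 89.6 and 100% were recovered, with 7 false calls of 166. The agonists within Treg gave 11.9, 64.2 and 98.5% with 5 false calls of 121. The test between cell types gave 7.46, 55.2 and 92.4% with 8 of 111. In the F-test 55.2, 85.1 and 100% were recovered with 6 of 166, and for 1 cell type against the others 86.6, 98.5 and 98.5% with 13 of 202. The changes were added only to genes with ample counts and were equal in all agonist libraries changed. The simulated libraries had no WT number, and their spread was estimated over all cell types. In the real data recovery may be lower and false calls more frequent, in Treg above all. A list raised on purpose was called by all 3 list tests, and 0 unchanged lists were.

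Alternatives were an absolute log2 fold change of at least 1 for the cell types, DESeq2 size factors in edgeR, no filter on low counts, limma-voom, DESeq2 1.42.0, the WT number as a block within cell type, the Th1 and CD8 libraries alone (where the number does not vary within a cell type), and leaving out each library in turn. Added after seeing the data were fits without the 6 Treg libraries, fits on 1 cell type alone, and gene length offsets, in which a smooth trend of count on gene length was removed from each library. The offsets were fitted on expressed genes, after a first version over all genes had left the trend in place. Counts were repeated over other groupings of the libraries, 100 drawn at random, or all 35 for 4 libraries against 4. In a check of the Treg and other within-type counts, each agonist library took the role of DMSO, in Treg also with DMSO left out, and with DMSO and WMS-200 left out. The correlation between compounds was compared with simulated compounds that share nothing but the DMSO libraries, in the fit without and with the WT number as a block and without each library in turn. No reads were available, so strand and isoforms were not examined.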

Results

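Messenger RNA was measured in 24 libraries of cultured mouse T cells, 6 from each of Th1, Th17, Treg and activated CD8 cells. Within a cell type 1 library had the vehicle DMSO and 5 had a KOR agonist at 0.1 µM. KOR is an opioid receptor that couples to inhibitory G proteins, and the labels call the agonists peripheral and derived from perhydroquinoxaline. The stated subject is how such compounds affect T cells. Total counts per library ran from 16933512 to 21946887 in Th1, from 16271300 to 21608525 in Th17, from 15188284 to 18500457 in Treg and from 16842562 to 20937496 in CD8. Replicates of a cell type carry different treatments, and no treatment was repeated within a cell type. The 6 Th1 libraries have 1 WT number, as have the 6 CD8 libraries, and libraries of a cell type may come from the same animal. The errors and p-values given below thus cover the spread between these libraries only.

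The receptor that the compounds target was barely detected. Oprk1, which encodes KOR, had 7 counts in all 24 libraries together, with a mean of 0.0468 CPM in Th1, 0.0167 in CD8 and 0 counts in every Th17 and Treg library. In the Th17 DMSO library a count of 0 allows up to 0.192 CPM. The transcripts of the other opioid receptors were also scarce, with 254 counts of Oprm1 (mu), 53 of Oprd1 (delta) and 82 of Oprl1 (nociceptin). Of the Oprm1 counts 164 lay in Treg (log2 fold change 2.23 ± 0.52 against the other cell types, adjusted p = 0.000358), with 3.11 CPM in DMSO and 0.973 ± 0.665 with the agonists (SD, n = 5), a difference of −1.66 ± 0.83 that did not pass (adjusted p = 0.228). The opioid peptide gene Penk, which encodes the enkephalin precursor, was abundant (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819 as the file gives it). It had 917 ± 73.0 CPM in Th1, 567 ± 27.96 in CD8, 96.1 ± 15.8 in Treg and 20.3 ± 8.19 in Th17 (SD, n = 6). Pomc, the precursor of beta-endorphin, lay between 1.27 and 2.48 CPM on average, and Pdyn, the precursor of the KOR ligand dynorphin, had 16 counts in all.

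The first comparison asks how each cell type differs from the mean of the other 3, and so whether the cultures carry the transcripts of their lineage. Th1 libraries were high in Ifng, the signature cytokine of these cells (log2 fold change 5.60 ± 0.12; ENSMUSG00000055170, chromosome 10, 118276951 to 118281797), in the interleukin 12 receptor chain Il12rb2 (2.44 ± 0.08) and in the lineage regulator Tbx21 (2.34 ± 0.05). Among genes whose 6 Th1 libraries all lay above every other library, the 6 largest rises were those of Sema3b (4.88 ± 0.14), Ifitm3 (4.71 ± 0.14), Dnah7a (4.35 ± 0.12), Stra6 (4.14 ± 0.12), Ermn (4.08 ± 0.11) and Ramp3 (4.00 ± 0.12). Il21 (3.41 ± 0.12), Il2 (2.24 ± 0.12) and Penk (3.15 ± 0.12) were higher too; the cytokine list had 11 higher and 6 lower of 18 and camera did not call it (adjusted p = 0.352). Low in Th1 were Itgae, the integrin of tissue-resident cells (−4.64 ± 0.16), the ectonucleotidase Nt5e (−3.70) and Maf (−3.17 ± 0.14). Of the 14 measured members of the Th1 program 8 were higher and 5 lower, and camera did not call this list (adjusted p = 0.259); the reference holds the CD8 libraries.

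Among gene groups in Th1, 15 of 17 glycolysis members were higher and 1 lower, as Hk2 (1.63 ± 0.06) and Tpi1 (1.57), with adjusted p = 5.24e-08 by camera and adjusted p = 0.380 with an estimated correlation. All 20 oxidative phosphorylation members were higher, as Cycs (0.98 ± 0.08) and Atp5b (0.84 ± 0.07), with 2.83e-07 and adjusted p = 0.380 with an estimated correlation. The integrated stress and unfolded protein response had 17 higher and 1 lower of 20, as Atf3 (1.70 ± 0.07), with 1.06e-05 and adjusted p = 0.380 with an estimated correlation. The interferon response had 10 higher and 2 lower of 17, as Gbp2 (2.29 ± 0.07) and Usp18 (1.71 ± 0.14), with 0.0268 and adjusted p = 0.380 with an estimated correlation. The 3 CD4 lineage genes were higher, as Cd40lg (1.39 ± 0.10) and Cd4 (1.01 ± 0.05), with 0.0148 and adjusted p = 0.380 with an estimated correlation. Heat shock had 8 higher and 1 lower of 11 (0.0148) and the Treg program 6 higher and 11 lower of 19 (0.0312), both with adjusted p = 0.402 with an estimated correlation. For apoptosis there were 9 higher and 1 lower of 14, and in the CD8 program 2 higher and 7 lower of 12, both with 0.0338 and adjusted p = 0.380 with an estimated correlation. In all, 9413 of 15885 genes passed with edgeR, 5051 higher and 4362 lower. No library of another cell type has the WT number of the Th1 libraries, so the number and the cell type cannot be told apart there.

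Th17 libraries carried the cytokines and receptors of their lineage. Il17f was higher by 9.30 ± 0.19 on the log2 scale (ENSMUSG00000041872, chromosome 1, 20847370 to 20860841), with 830 ± 121 CPM against 1.06 in Th1 (n = 6 each). Il17a (4.97 ± 0.17), Il22 (4.21 ± 0.24), Maf (4.86 ± 0.10), Ccr6 (3.63 ± 0.15) and Ahr (3.05 ± 0.05) were high as well. Among genes whose 6 Th17 libraries all lay above every other library, Il17f was followed by Olfm2 (7.54 ± 0.13), the glycerol channel Aqp3 (6.62 ± 0.09), Crispld2 (6.26 ± 0.15), the homing receptor Gpr15 (5.72 ± 0.22) and Tmem176a (5.63 ± 0.08). The Th17 program had 15 of 16 members higher and none lower, with adjusted p = 5.38e-11 by camera and adjusted p = 0.0102 with an estimated correlation. Il10, an anti-inflammatory cytokine, rose by 3.84 ± 0.22. Il23r was at 0.29 ± 0.23 and did not pass (adjusted p = 0.290).

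The Th1 program was low in Th17, with 3 higher and 10 lower of 14, among them Il12rb2 (−4.28 ± 0.11), Ifng (−3.57) and Tbx21 (−3.49 ± 0.07); camera gave 0.000152 and adjusted p = 0.0102 with an estimated correlation. The interferon response had 15 of 17 members lower and none higher, as Iigp1 (−5.99 ± 0.18), Gbp2 (−3.00) and Mx1 (−2.99), with 9.46e-09 and adjusted p = 0.00932 with an estimated correlation. Lysosome genes had 12 higher and none lower of 19, as Psap (1.10) and Lamp2 (0.76), with 0.000766 and adjusted p = 0.220 with an estimated correlation. Oxidative phosphorylation had 19 of 20 higher (0.000411), mitochondrially encoded genes 11 of 12 lower, as mt-Co2 (−1.58; 0.00166), and the integrated stress list 10 higher and 2 lower of 20 (0.0493), all with adjusted p = 0.519 with an estimated correlation. Proliferation had 14 higher and 1 lower of 22 (0.0232, and adjusted p = 0.673 with an estimated correlation), and glycolysis 2 higher and 8 lower of 17 (0.0493, and adjusted p = 0.545 with an estimated correlation). Apoptosis had 1 higher and 8 lower of 14 (0.00491, and adjusted p = 0.194 with an estimated correlation). B cell markers had 1 higher and 8 lower of 10 (0.0329, and adjusted p = 0.331 with an estimated correlation). All 3 measured opioid genes were lower, Penk by −4.21 ± 0.17 (0.0493, and adjusted p = 0.219 with an estimated correlation). With edgeR 9107 genes passed, 5022 higher and 4085 lower.

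Treg libraries stood furthest from the rest. Foxp3, the regulator that defines the lineage, was higher by 4.85 ± 0.15 (ENSMUSG00000039521, chromosome X, 7439883 to 7461484), with 281 ± 79.9 CPM against 33.9 ± 4.06 in Th17 (n = 6 each). Ikzf2, a Treg transcription factor (5.88 ± 0.14), Itgae (5.57 ± 0.10), Lrrc32, which anchors latent TGF-beta (3.61 ± 0.12), and the inhibitory receptor Ctla4 (1.80 ± 0.07) were also higher. By the same rule the largest rises, with Ikzf2 and Itgae, were those of Sspo (6.96 ± 0.21), Matk (5.89 ± 0.15), Rgs9 (5.67 ± 0.13) and Pde4a (5.50 ± 0.12). The Treg program had 14 members higher and 3 lower of 19, with adjusted p = 0.00173 by camera and adjusted p = 0.315 with an estimated correlation. Effector cytokine genes were low, with Il21 at −9.39 ± 0.22, Ifng at −9.24 ± 0.23 and Il2 at −5.74 ± 0.19; the cytokine list had 4 higher and 12 lower of 18 (0.0326, and adjusted p = 0.591 with an estimated correlation).

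Several metabolic and stress lists had most members lower in Treg. The log2 fold changes of Treg followed gene length, with a rank correlation of 0.320 over 11483 genes and 0.0215 with length offsets. All 20 oxidative phosphorylation members were lower, as Ndufa1 (−2.64) and Uqcrq (−2.60), with 5.37e-08, and so were all 20 of the integrated stress list, as Trib3 (−2.73) and Atf3 (−3.45), with 6.80e-08. Glycolysis had 14 lower and 1 higher of 17, as Pgk1 (−3.02) and Tpi1 (−2.90), with 8.47e-06. Hypoxia had 10 lower and 2 higher of 14 (0.0222) and the CD8 program 10 lower and 1 higher of 12, as Gzmb (−6.37 ± 0.19) and Prf1 (−5.04; 0.00439). These 5 lists each had adjusted p = 0.315 with an estimated correlation. With length offsets 4 named genes had the opposite sign in Treg: Klrd1 of the CD8 program (0.46 in place of −0.33), Tnf of the cytokine list and the Th1 program (0.31 in place of −0.28), and Nkg7 (0.66 in place of −0.35) and Fasl (0.33 in place of −0.15) of the Th1 program. Beside them stands the composition of the libraries, in which ribosomal protein genes took 2.36 ± 0.42% of the counts in Treg against 12.2 ± 0.51% in Th1, 11.9 ± 1.20% in Th17 and 10.8 ± 0.34% in CD8 (SD, n = 6). Mitochondrially encoded genes took 1.13 ± 0.22% against 0.484, 0.336 and 0.572%. The 4 measured sex-linked genes were higher (0.0368, and adjusted p = 0.386 with an estimated correlation). With edgeR 12779 genes passed, 6760 higher and 6019 lower. Treg libraries are in the mean of the other cell types, so the Th1, Th17 and CD8 values of these groups contain the Treg difference.

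CD8 libraries, named Tc1 in the column names, carried cytotoxic genes and inflammatory chemokines. Ifng was higher by 7.21 ± 0.12, Gzmb, a granule protease, by 5.32 ± 0.12 (1911 ± 75.7 CPM), the pore-forming Prf1 by 4.37 ± 0.12 and Cd8a by 4.26 ± 0.12 (ENSMUSG00000053977, chromosome 6, 71350411 to 71356157). Other large rises were those of Selp (5.37 ± 0.16), Ccl9 (5.33 ± 0.15), Plac8 (4.77 ± 0.10), Ccl3 (3.99), Xcl1 (3.66) and Ccl5 (3.65 ± 0.12). The CD8 program had 10 members higher and none lower of 12, as Eomes (2.84 ± 0.13), with 2.98e-07 and adjusted p = 0.0277 with an estimated correlation. The Th1 program had 12 higher and none lower of 14, as Tbx21 (2.55 ± 0.05), with 1.63e-06 and adjusted p = 0.00661 with an estimated correlation. The CD4 lineage genes were lower, Cd4 by −1.73 ± 0.06 and Zbtb7b by −0.75, in 3 of 3 (0.00441, and adjusted p = 0.142 with an estimated correlation).

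Glycolysis had 16 of 17 members higher in CD8, as Hk2 (2.08) and Tpi1 (1.81; 8.40e-09), the integrated stress list 17 of 20, as Atf3 (1.79; 1.39e-06), and none lower in either. The Treg program had 15 lower and 3 higher of 19, as Foxp3 (−3.48 ± 0.22) and Lrrc32 (−2.73; 7.90e-06). These 3 lists had adjusted p = 0.142 with an estimated correlation. Oxidative phosphorylation had 20 of 20 higher (2.98e-07, and adjusted p = 0.262 with an estimated correlation), and hypoxia 9 higher and 2 lower of 14 (0.00798, and adjusted p = 0.167 with an estimated correlation). Immediate early genes had 13 higher and 3 lower of 21, as Nr4a2 (1.87) and Fos (1.36; 0.0102, and adjusted p = 0.441 with an estimated correlation). The cytokine list had 11 higher and 4 lower of 18 (0.0164, and adjusted p = 0.402 with an estimated correlation). The Th17 program had 4 higher and 10 lower of 16, as Ccr6 (−5.01; 0.00461, and adjusted p = 0.231 with an estimated correlation). Apoptosis had 9 higher of 14 (0.00798, and adjusted p = 0.159 with an estimated correlation). With edgeR 9324 genes passed, 5121 higher and 4203 lower. By itself each list was also tested with fry, which called 22 of 29 lists in Th1, 24 in Th17, 27 in Treg and 24 in CD8.

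**Figure D1:**
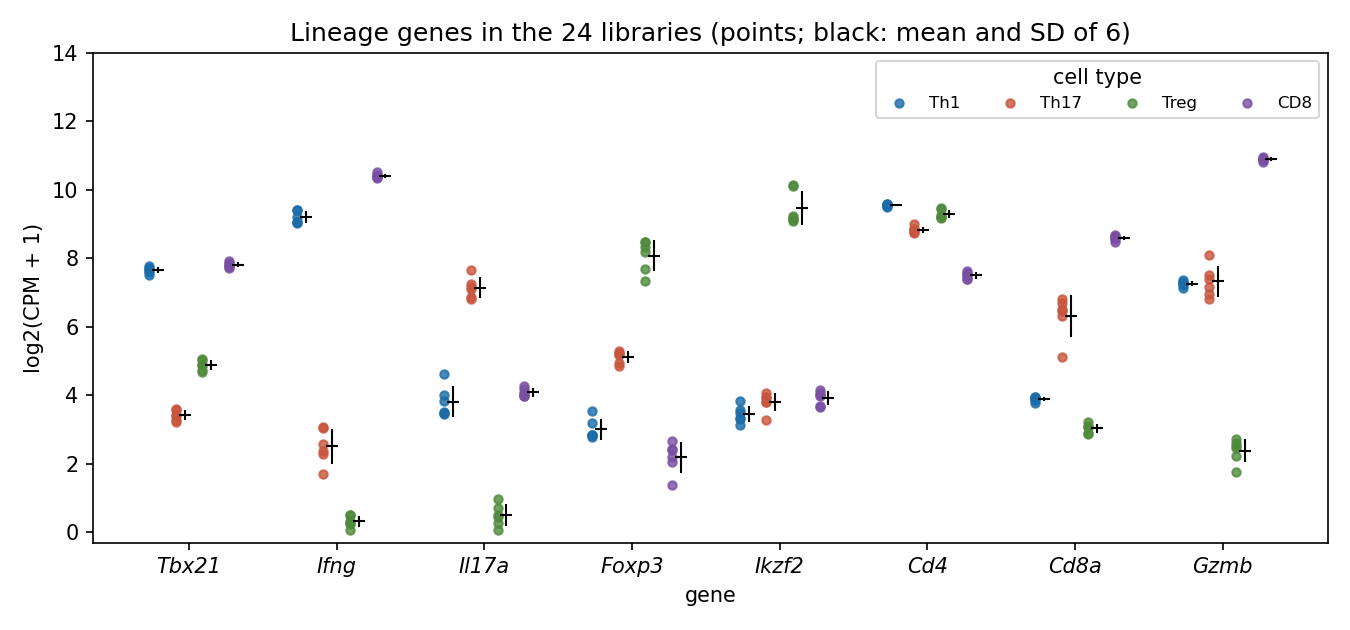
Expression, as log2 of CPM plus 1, of 8 lineage genes in the 4 cell types; coloured points are the 6 libraries of a cell type, and black marks are their mean and SD. Il17a is highest in Th17, Foxp3 and Ikzf2 in Treg, and Cd8a and Gzmb in CD8.

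Adjusted over the list alone, the counts of most lists were those over all genes. In Th1 they became 18 higher and 1 lower for integrated stress and 6 higher and 12 lower for the Treg program. In Th17 they became 12 higher and 2 lower for integrated stress and 12 lower for mitochondrially encoded genes. In CD8 they became 12 higher and 1 lower for the Th1 program and 10 higher for apoptosis. Lists that camera did not call had members on both sides. In Th1, Th17, Treg and CD8 in turn, the counts higher and lower were 6 and 3, 5 and 4, 3 and 6, and 9 and 2 for the 13 p53 genes, and 10 and 9, 8 and 9, 9 and 9, and 7 and 7 for the 21 G protein and cAMP genes. They were 6 and 4, 1 and 5, 3 and 6, and 7 and 3 for the 11 inhibitory receptors, and 5 and 6, 5 and 5, 5 and 6, and 6 and 4 for the 12 naive and memory genes. The 8 Th2 genes gave 2 and 4, 5 and 2, 3 and 4, and 2 and 4, among them Gata3 at 2.03 ± 0.06 in Treg. The 21 cholesterol synthesis genes gave 4 and 4, 10 and 3, 3 and 13, and 5 and 2.

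Markers of other cells were counted in every cell type. Over the whole list, B cell markers summed to 147 ± 18.7 CPM in Treg against 62.5, 56.5 and 86.3 in Th1, Th17 and CD8, myeloid and dendritic markers to 280 ± 11.1 in Th1 against 125, 178 and 252 in Th17, Treg and CD8, and NK and gamma delta markers to 21.8 ± 3.59 in Th17 against 7.30, 6.08 and 14.8 in Th1, Treg and CD8. Stromal markers summed to 54.9 ± 4.70 in Treg against 21.3, 16.8 and 18.5 in Th1, Th17 and CD8, and erythroid markers to 1.24 in Treg against 0.309, 0.660 and 0.729. By camera only the B cell markers in Th17 were called among these lists and cell types, and the erythroid list was not tested.

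The next comparison asks what KOR agonists do to T cells in general, over the 4 cell types. No gene was called for the 5 agonists together against DMSO. The nearest were Matk, a kinase gene (−0.86 ± 0.21), the interferon-induced Gbp5 (0.26 ± 0.07, interval 0.13 to 0.40), Arhgap20 (−0.75 ± 0.19), H2-Q6 (−1.10 ± 0.28) and Prxl2a (−0.38 ± 0.10), each with adjusted p = 0.992; H2-Q6 has close paralogs. The estimates were tight, with an interval within 0.5 of 0 on the log2 scale for 86.3% of 11483 expressed genes and within 1 for 99.4%. Penk was at −0.17 ± 0.15 (interval −0.49 to 0.16). Counts were 0 with edgeR and 0 with DESeq2, 5 with limma-voom, and 504 at an unadjusted p under 0.05, where chance alone gives 794.

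For single compounds, called genes were 0 for each with edgeR and with DESeq2. Unadjusted p under 0.05 was reached by 246 genes for WMS-200, 1021 for WMS-64, 548 for WMS-75, 488 for WMS-76 and 620 for WMS-83, where chance alone gives 794, so WMS-64 lay above that number and the other 4 below it. With limma-voom the counts were 0, 5, 4, 3 and 3. Arhgap20 was the nearest to a call for WMS-76 (−1.35 ± 0.27, adjusted p = 0.541) and was at −1.29 ± 0.27 for WMS-83 (adjusted p = 0.915). The interval lay within 0.5 of 0 for 79.5, 74.97, 77.5, 77.1 and 75.9% of expressed genes, and within 1 for 97.8, 96.9, 97.0, 97.0 and 96.8%.

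Immediate early genes, which T cells induce on receptor stimulation, had a median log2 fold change of 0.13 over 21 members under the agonists, taken over the 4 cell types. Camera gave adjusted p = 2.38e-06, and adjusted p = 0.669 with an estimated correlation; 0 members passed over all genes and 2 adjusted over the list alone. Camera called the same list for each compound, with 0.000682 for WMS-200, 0.00151 for WMS-64, 0.00120 for WMS-75, 0.000154 for WMS-76 and 0.000125 for WMS-83. For these, in turn, adjusted p = 0.990, 0.762, 0.926, 0.637 and 0.514 with an estimated correlation. In the Th1 and CD8 libraries alone, where the WT number does not vary within a cell type, the direction of this list turned downward, without a call, for the agonists (camera adjusted p = 0.934), WMS-64, WMS-75, WMS-76 and WMS-83, and stayed upward for WMS-200. The agonists' other lists at a preset correlation, all upward, were apoptosis, cholesterol synthesis, glycolysis, heat shock, inhibitory receptors, proliferation and the Treg program, with camera values of 0.0191 to 0.0415 and adjusted p = 0.669 to 0.747 with an estimated correlation. Heat shock and cholesterol synthesis turned downward, without a call, both with the WT number as a block (adjusted p = 0.925 and 0.839) and with Th1 and CD8 alone (0.152 and 0.934), and inhibitory receptors with Th1 and CD8 alone (0.945). WMS-83 had the CD8 program lower (median −0.30, 0.000482, and adjusted p = 0.446 with an estimated correlation). WMS-75 had mitochondrially encoded genes higher (median 0.36, 0.00231), and the integrated stress list (median −0.0975, 0.00231), lysosome (−0.0815, 0.00454) and oxidative phosphorylation (−0.0881, 0.0396) lower, each with adjusted p = 0.926 with an estimated correlation. The Th17 WMS-75 library stood apart in composition. Mitochondrially encoded genes took 0.553% of its counts, against 0.215 to 0.364% in the other Th17 libraries, and ribosomal protein genes 9.74%, against 11.5 to 12.9%. The mitochondrial share with WMS-75 was also the highest in Th1 (0.664%), but not in Treg (1.04%) or CD8 (0.520%). In total camera called 1, 7, 5, 10 and 10 lists for the 5 compounds, an estimated correlation 0 and fry 0. With the WT number as a block the agonists' 8 lists became 0, and the counts of the compounds became 0, 1, 5, 0 and 0. The 1 was glycolysis, upward, for WMS-64. The 5 for WMS-75, all downward, were oxidative phosphorylation (0.000298), integrated stress (0.00119), heat shock, lysosome and cytokines, while its immediate early and mitochondrially encoded lists were not called (0.699 and 0.150). In Th1 and CD8 alone camera called 4 of these 5 downward for WMS-75, all but lysosome, and also called integrated stress for WMS-76 and glycolysis for WMS-83, both downward (0.0200 and 0.0229).

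Compounds were then compared with one another at the same dose. Arhgap20, a GTPase-activating gene (ENSMUSG00000053199, chromosome 9, 51676637 to 51765156), was the only gene edgeR called in a pair, and it was 3.11-fold higher with WMS-200 than with WMS-76 (log2 1.64 ± 0.26, interval 1.10 to 2.18, adjusted p = 0.0257). In Treg it had 93.0 CPM with WMS-200 and 23.03 with WMS-76, against 69.5 in DMSO, and 32.1, 31.4 and 23.5 with WMS-64, WMS-75 and WMS-83. In the other 3 cell types Arhgap20 lay between 0.263 and 1.85 CPM in every library. The call was lost (0 genes) with the WT number as a block, with the Th1 and CD8 libraries alone and without the 6 Treg libraries. It was also lost without Th1 WMS-76, Th17 WMS-200, Treg WMS-200, Treg WMS-76 or CD8 WMS-76 (0 genes in each case, Arhgap20 at 1.23 to 1.72).

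The other 9 pairs gave 0 genes with edgeR. Their genes at an unadjusted p under 0.05 numbered 635 for WMS-200 and WMS-64, 525 for WMS-200 and WMS-75, 673 for WMS-200 and WMS-83, 1382 for WMS-64 and WMS-75, 262 for WMS-64 and WMS-76, 516 for WMS-64 and WMS-83, 540 for WMS-75 and WMS-76, 1087 for WMS-75 and WMS-83, and 286 for WMS-76 and WMS-83; the pairs of WMS-75 with WMS-64 and with WMS-83 lay above the 794 of chance. Limma-voom called 3 genes for WMS-200 and WMS-64, 1 for WMS-200 and WMS-75, 1 for WMS-200 and WMS-83 and 1 for WMS-64 and WMS-83; DESeq2 called 1 for WMS-200 and WMS-75, 1 for WMS-200 and WMS-83 and 5 for WMS-75 and WMS-83; either tool called 0 in the remaining pairs. Of the expressed genes, 74.1 to 80.1% had an interval of the difference within 0.5 of 0, and 96.3 to 97.9% within 1, so differences over 0.5 are not excluded for the genes outside the first range, nor differences over 1 for those outside the second. The F-test among the 5 agonists called 0 genes with edgeR, 3 with limma-voom and 2 with DESeq2, with 444 at an unadjusted p under 0.05; its smallest adjusted p was 0.0584, for Arhgap20. Leaving out 1 library gave 1 gene in the F-test without Th1 WMS-75, Th17 WMS-75, Th17 WMS-76 or Treg WMS-75, and 2 without Treg DMSO. WMS-200 against WMS-75 gave 1 without Treg DMSO. WMS-200 against WMS-83 gave 1 without Th1 WMS-200, Th1 WMS-75, Th1 WMS-76, Th17 WMS-75, Th17 WMS-76, Treg DMSO, Treg WMS-75 or CD8 WMS-200.

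Whether compounds share an effect was asked from the correlation of their fold changes across 11483 genes, which are not independent replicates. The 10 pairs had a median r of 0.446 (0.364 to 0.697). All compounds share the 4 DMSO libraries, and simulated compounds with nothing else in common gave a median r of 0.5002 (0.486 to 0.518 in 20 simulations). With the controls split, each compound of a pair was set against DMSO in different cell types, so that no library served both compounds. The median r was then −0.0752 (−0.172 to −0.00565). An effect that compounds share within a cell type cannot show in this split. Over all libraries the median thus did not exceed that of the common controls. The 3 pairs among WMS-64, WMS-76 and WMS-83 lay above their simulated values, with r = 0.697 for WMS-64 and WMS-76 (simulated 0.472 to 0.5295), 0.633 for WMS-64 and WMS-83 (0.465 to 0.5196) and 0.659 for WMS-76 and WMS-83 (0.4798 to 0.522), and at −0.00565, −0.0486 and −0.0756 with the controls split. These 3 compounds and WMS-75 have 1 WT number in Treg, which the simulation leaves out, and a shared effect of the 3 stays open. With the number as a block the median r was 0.559, against a simulated 0.594 (0.580 to 0.604) in the same fit, and these pairs were at 0.669 (simulated 0.6251 to 0.6656), 0.524 (0.579 to 0.612) and 0.598 (0.579 to 0.605), while WMS-200 lay above its simulated values with WMS-64 (0.5997, simulated 0.553 to 0.589) and WMS-76 (0.605, simulated 0.550 to 0.595). Without 1 library the median r lay above its own simulated range in 4 of 24 cases: without Th1 DMSO (0.615, simulated 0.575 to 0.600), CD8 DMSO (0.614, simulated 0.568 to 0.599), Th17 WMS-75 (0.513, simulated 0.472 to 0.509) or Treg WMS-200 (0.541, simulated 0.468 to 0.505). It lay within its range without Th17 DMSO (0.578, simulated 0.573 to 0.596). In all other cases it lay below, as without Treg DMSO (0.492, simulated 0.568 to 0.600), and so did the median over all libraries. The simulation thus does not match the level of the real correlations in most cases, and sharing between compounds stays open.

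The last comparisons set the agonists against DMSO inside each cell type. In Th1 no gene was called; the nearest, H2-Q6, was at −2.17 ± 0.41 (adjusted p = 0.237), and Penk was at 0.01 ± 0.13 (interval −0.25 to 0.27). Counts were 0 with edgeR, 0 with limma-voom and 3 with DESeq2, with 517 genes at an unadjusted p under 0.05, and 1 gene with edgeR without CD8 WMS-64. Mitochondrially encoded genes leaned upward in Th1 (median 0.60; camera 0.00120, and adjusted p = 0.956 with an estimated correlation). In CD8 the same list leaned downward (median −0.50; camera 0.000600, and adjusted p = 0.917 with an estimated correlation). The only gene called in CD8 was the processed pseudogene Gm2606 (−3.48 ± 0.46, adjusted p = 0.000373; chromosome 15, 12574975 to 12575976), lower in all 5 agonist libraries and named after its values were seen. Reads of a pseudogene and of its parent gene cannot be separated with certainty. Intervals lay within 0.5 of 0 for 59.0% of genes in Th1 and 61.4% in CD8.

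In Th17, Penk was lower with every agonist. It had 36.7 CPM with DMSO and 17.0 ± 1.86 with the agonists (SD, n = 5), a log2 fold change of −1.11 ± 0.13 (interval −1.38 to −0.83, adjusted p = 6.28e-05). Gzmb fell by 0.90 ± 0.15 on the log2 scale (adjusted p = 0.0116), Akap1, a mitochondrial anchor of protein kinase A, by 0.93 ± 0.15 (0.00831) and Rnf157, a ubiquitin ligase gene, by 0.77 ± 0.15 (0.0426). Spry1, an inhibitor of receptor tyrosine kinase signalling, rose by 0.74 ± 0.13 (0.0116) and Fasl, the death receptor ligand, by 1.55 ± 0.29 (0.0244). Markers of other cells were compared as well. NK and gamma delta markers summed to 26.1 CPM with DMSO and 16.4 to 23.6 with the agonists. Myeloid and dendritic markers summed to 138 CPM with DMSO and 99.8 to 136 with the agonists. B cell, erythroid and stromal sums with DMSO lay within the range of the agonists. These sums rest on 1 DMSO library, and for the agonists in Th17 camera called no marker list. Il17f (0.18 ± 0.33) and Il17a (0.08 ± 0.38) did not pass and were looked up after the calls were known (adjusted p = 1 each).

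These 6 genes were all that edgeR called in Th17. By camera the immediate early list leaned upward (median 0.17, 8.60e-07, and adjusted p = 0.138 with an estimated correlation), with 0 members called over all genes and 5 higher and 1 lower adjusted over the list alone. Proliferation (median −0.27, 9.86e-06, and adjusted p = 0.629 with an estimated correlation) and the CD8 program (median −0.38, 0.000995, and adjusted p = 0.256 with an estimated correlation) leaned downward. Inhibitory receptors (median 0.22, 0.00392, and adjusted p = 0.0913 with an estimated correlation) and naive and memory genes (median 0.09, 0.00262, and adjusted p = 0.256 with an estimated correlation) leaned upward, and the 3 opioid genes downward (0.00262, and adjusted p = 0.0716 with an estimated correlation; fry 0.00356). No other Th17 library has the WT number 2 of DMSO, so the block of the number and the treatment cannot be told apart, and the Th17 libraries fitted alone gave 0 genes. Rnf157 lost its call with DESeq2 size factors, with length offsets and without any 1 of Th1 WMS-200, WMS-64, WMS-75 or WMS-76, Th17 WMS-200, WMS-64, WMS-75 or WMS-76, or CD8 WMS-200, WMS-64, WMS-75, WMS-76 or WMS-83 (log2 −0.75 to −0.77 without 1 of these). Fasl lost its call with limma-voom and without Th17 WMS-200.

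**Figure D2:**
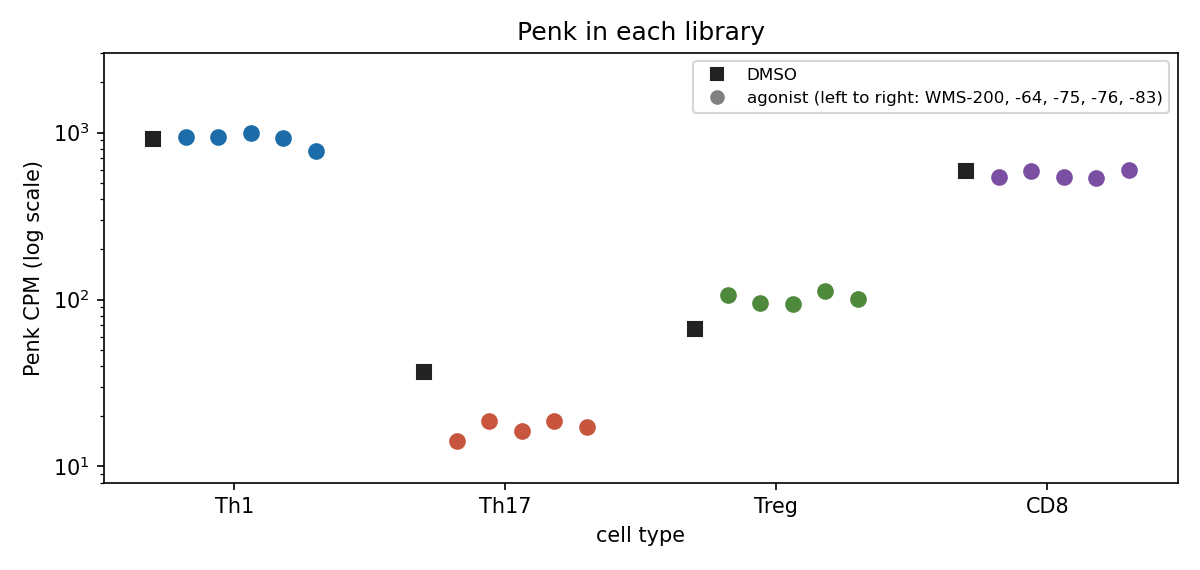
Penk in CPM on a log axis in each of the 24 libraries, grouped by cell type, with DMSO beside the 5 agonists. In Th17 DMSO lies at 36.7 CPM, above all 5 agonist libraries; in Treg DMSO lies at 67.0 CPM and the agonists at 102 ± 7.62 (SD, n = 5).

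In Treg 1401 genes differed between the agonist libraries and the 1 DMSO library. Only WMS-200 has the WT number of DMSO. With the number as a block the fit in Treg thus left WMS-200 against DMSO, 1 library each, and most of these calls were lost. Fewer libraries by themselves lower the number of calls, so that loss does not tell the number from the agonists. Il2ra, the high-affinity interleukin 2 receptor chain, rose by 1.05 ± 0.16 (adjusted p = 0.000821; ENSMUSG00000026770, chromosome 2, 11647618 to 11698004), Egr3 by 1.02 ± 0.16, Myc by 0.82 ± 0.14 and the cytokine Csf2 by 1.64 ± 0.29. The largest rises by the rule were those of complement C3 (3.50 ± 0.77; chromosome 17, 57510970 to 57535136), Apba1 (3.15 ± 0.89), Mical2 (3.11 ± 0.58), Nrgn (2.89 ± 0.66), Spp1 (2.75 ± 0.63), Cadm1 (2.31), Rai14 (2.29) and Hmgn2-ps, a pseudogene symbol (2.20 ± 0.31). The largest falls were those of Tubg2 (0.353 times the DMSO level), Erdr1 (−1.46 ± 0.32), Matk (−1.39 ± 0.27), H2-Q6 (−1.28), Usp18 (−1.19 ± 0.26), Zfr2 (−1.17) and Slc7a3 (−1.14). Penk rose by 0.60 ± 0.14. Markers of other cells were compared too. Myeloid and dendritic markers summed to 137 CPM with DMSO and 167 to 219 with the agonists. B cell markers summed to 167 CPM with DMSO and 118 to 164 with the agonists, highest with WMS-200, which has the WT number of DMSO. Erythroid and platelet markers summed to 2.003 CPM with DMSO and 0.4435 to 1.76 with the agonists. NK and gamma delta and stromal sums with DMSO lay within the range of the agonists. These sums rest on 1 DMSO library. For the agonists in Treg camera called no marker list, and the erythroid list was not tested.

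By group in Treg, proliferation had 15 of 22 members higher and none lower, as Rrm2 (1.05 ± 0.21) and Birc5 (0.92), with camera adjusted p = 4.81e-10, adjusted p = 0.297 with an estimated correlation and adjusted p = 0.0650 with the WT number as a block. Immediate early genes had 11 of 21 higher (7.84e-06, and adjusted p = 0.237 with an estimated correlation). Heat shock had 7 of 11 higher, as Hsp90aa1 (0.92 ± 0.17) and Hspa1a (1.66 ± 0.42; 1.80e-05), and the cytokine list 7 higher and 1 lower of 18, as Tnf (1.02 ± 0.22; 0.000328), both with adjusted p = 0.297 with an estimated correlation. Glycolysis had 7 higher and 1 lower of 17, as the glucose transporter Slc2a1 (0.92 ± 0.15) and Slc2a3 (−0.61 ± 0.12; 0.000590, and adjusted p = 0.377 with an estimated correlation). Oxidative phosphorylation had 6 of 20 higher, as Ndufa4 (1.04 ± 0.20; 8.50e-05, and adjusted p = 0.415 with an estimated correlation). Cholesterol synthesis had 7 of 21 higher (0.000328, and adjusted p = 0.494 with an estimated correlation), and with the WT number as a block its direction was downward (adjusted p = 0.830). The ribosomal protein share, which differs most between Treg and the rest, was 1.74% with DMSO and 2.15, 2.95, 2.34, 2.30 and 2.70% with WMS-200, WMS-64, WMS-75, WMS-76 and WMS-83. The log2 fold changes of the agonists in Treg followed gene length with a rank correlation of −0.220 over 11483 genes, and −0.0286 with length offsets. The myeloid and dendritic, B cell and erythroid markers given above, none of them called, also differed between DMSO and the agonists.

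The Th17 program in Treg had 3 of 16 members higher and none lower (camera 0.00159, and adjusted p = 0.0486 with an estimated correlation), among them Maf (0.80 ± 0.17, adjusted p = 0.00604), named after its value was seen. The Treg program had 5 of 19 higher, as Lrrc32 (1.38 ± 0.28), with 0.00579 and adjusted p = 0.297 with an estimated correlation; Foxp3 itself (0.91 ± 0.29, adjusted p = 0.0542) and Ikzf2 (−0.75 ± 0.28, adjusted p = 0.114) did not pass and were looked up in the same way. Without Treg WMS-200 both passed (Foxp3 at 1.02, Ikzf2 at −0.998), and Foxp3 also passed with limma-voom and without CD8 WMS-64 or CD8 WMS-83 (0.91 in both cases). With the WT number as a block Maf was at 0.30 and not called. The interferon response had 4 lower and 1 higher of 17, as Usp18 and Gbp4 (−0.95 ± 0.23), with 0.00579 and adjusted p = 0.237 with an estimated correlation. The Th2 program had 1 higher of 8 (0.0403) and the sex-linked list 1 lower of 4 (Uty, −0.51; 0.0194), both with adjusted p = 0.297 with an estimated correlation. Adjusted over the list alone, the counts higher and lower were 21 and 0 for proliferation, 13 and 0 for immediate early, 9 and 0 for heat shock, 10 and 1 for cytokines, 11 and 1 for glycolysis, 8 and 0 for oxidative phosphorylation, 11 and 0 for cholesterol, 6 and 0 for the Th17 program, 12 and 1 for the Treg program and 2 and 6 for interferon; those of the Th2 program and the sex-linked list stayed at 1 and 0 and at 0 and 1.

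In all, 1401 genes were called in Treg with edgeR, 1213 higher and 188 lower. With DESeq2 size factors there were 997, 760 higher and 237 lower, so that 76.2 in place of 86.6% of the called genes were higher. The share of called genes that were higher was lower still with limma-voom and with length offsets. The spread behind the Treg calls was pooled over the 4 cell types. Between libraries of 1 cell type, pairs with DMSO included, the median chi-square per degree of freedom was 20.8 in Treg, 6.80 in Th1, 10.6 in Th17 and 6.66 in CD8. The pooled spread may thus be too small for Treg, and its adjusted p too low. DMSO and WMS-200 share WT number 3 and the other 4 agonists have number 2. With the number as a block the agonist effect was that of WMS-200 against DMSO, 1 library each, and not that of the 5 agonists. Of the genes named here Slc2a1 and Hmgn2-ps were still called. The term for the number was WMS-200 against the other 4 agonists. It may thus hold a difference between compounds or 1 library standing apart as well as the number. Under that block camera at the preset correlation called 6 of the 12 lists: the Th17 program (0.0315, and adjusted p = 0.298 with an estimated correlation), immediate early genes (4.21e-05, and adjusted p = 0.402), cytokines (0.0119, and adjusted p = 0.63), and glycolysis (0.00858), oxidative phosphorylation (0.0315) and heat shock (0.0203), these 3 with adjusted p = 0.666 with an estimated correlation. The calls of proliferation and the Treg program (0.0650 each), the interferon response (0.532), cholesterol synthesis (0.830), the Th2 program (0.481) and the sex-linked list (0.378) were lost. The 6 Treg libraries fitted alone gave 3 genes. Without Treg WMS-200 the count was 2649. Limma-voom ended the calls of C3, Apba1, Mical2, Spp1, Cadm1, Rai14, Birc5 and Hspa1a, DESeq2 those of Apba1 and Nrgn, and length offsets that of Penk. With another Treg library in the role of DMSO the count was 51 for WMS-200, sharing 0 genes with the 1401, and 0 for each of the other 4; with DMSO left out WMS-200 against the other 4 agonists gave 1237 genes, 355 of them among the 1401.

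**Figure D3:**
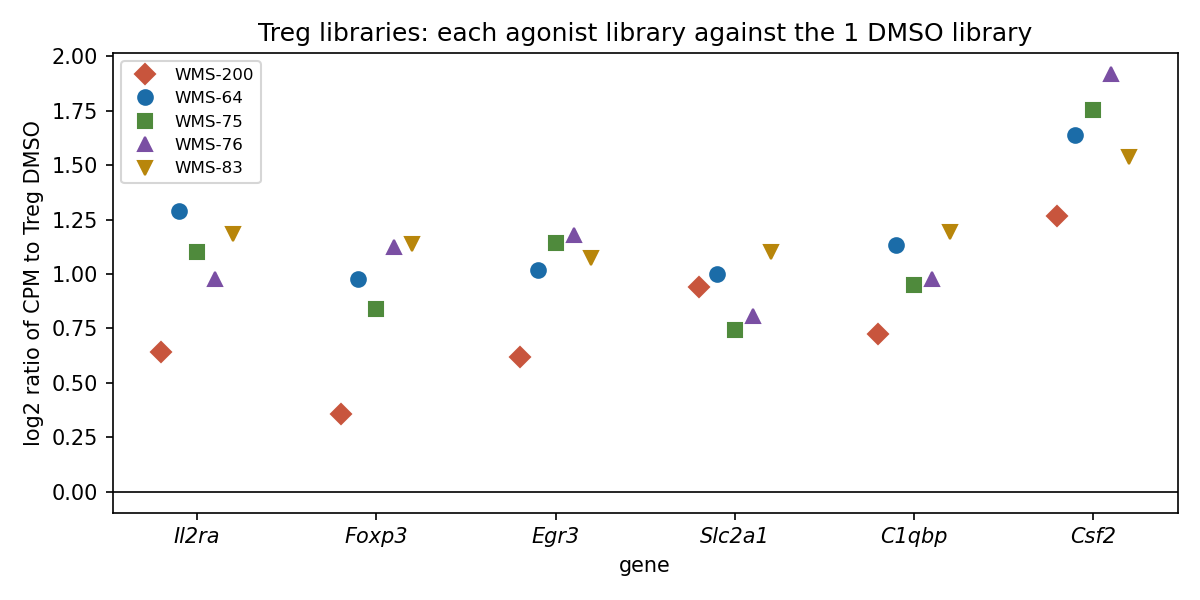
Log2 ratio of CPM to the Treg DMSO library for Il2ra, Foxp3, Egr3, Slc2a1, C1qbp and Csf2 in the 5 Treg agonist libraries, 1 point per library. WMS-200, which has the WT number of DMSO, is shown beside the other 4; Il2ra had 563 CPM with DMSO, 877 with WMS-200 and 1109 to 1374 with the other 4.

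**Figure D4:**
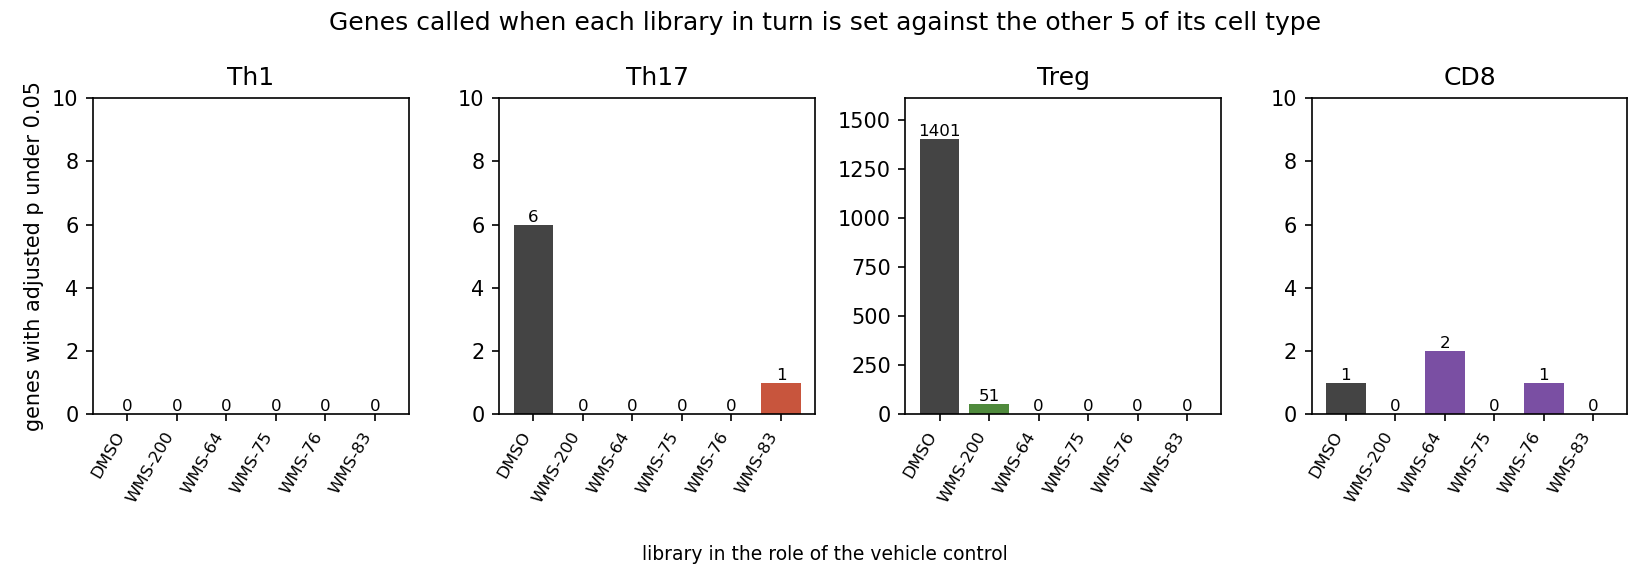
Number of genes called when each of the 6 libraries of a cell type takes the role of DMSO, 1 panel per cell type, each with its own vertical scale. The Treg panel reaches 1401 with DMSO and 51 with WMS-200; Th17 reaches 6 with DMSO, and CD8 reaches 2 with WMS-64.

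Whether the agonist effect differs between cell types was tested gene by gene, and 28 genes were called with edgeR. Penk was first (adjusted p = 0.000195), at 0.01 in Th1, −1.11 in Th17, 0.60 in Treg and −0.06 in CD8. Il2ra (adjusted p = 0.0279) was at −0.04, 0.03, 1.05 and −0.08 in these cell types, and C1qbp, a mitochondrial matrix protein gene (0.0266), at −0.06, 0.10, 1.00 and −0.04. Csf2 (0.0266) was at −0.10, −0.74, 1.64 and −0.46, and Gzmb (0.0279) at 0.07, −0.90, 0.97 and −0.09. The effect was largest in Treg for 26 of the 28 genes and in Th17 for 2, Penk and Akap1. C1qbp lost its call with limma-voom and Gzmb with length offsets. In Treg and Th17 the WT number runs along with the treatment here too, and the spread is again pooled over the cell types. The count moved with single libraries. It was 10 without Th1 WMS-200, 12 without Th1 WMS-64, 11 without Th1 WMS-75, 18 without Th1 WMS-76, 11 without Th17 WMS-200, 16 without Th17 WMS-64, 124 without Th17 WMS-75, 55 without Th17 WMS-76, 1032 without Treg WMS-200, 17 without Treg WMS-64, 12 without CD8 WMS-200, 12 without CD8 WMS-75 and 11 without CD8 WMS-83. It was 12 with DESeq2 size factors, 12 with limma-voom, 353 with DESeq2, 811 without a filter on low counts and 15 with length offsets.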

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

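All tests weighed here for the Treg libraries were chosen after the result was seen, as were the groupings for WMS-200 against DMSO and for the F-test; the other groupings of libraries were chosen before.

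The agonist effect differed between cell types for 28 genes by the interaction test. The 10 with the smallest adjusted p were Penk (0.000195), Impdh2-ps (0.0127), Siah1b (0.0146), Prpf31 (0.0167), Hmgn2-ps (0.0167), Csf2 (0.0266), C1qbp (0.0266), Gzmb (0.0279), Il2ra (0.0279) and Cdca5 (0.0279). Siah1b was at 2.17 ± 0.34 in Treg, Prpf31 at 0.89 ± 0.13, Cdca5 at 1.07 ± 0.18 and Impdh2-ps at 1.05 ± 0.15, against values between −0.66 (Siah1b in Th1) and 0.0151 (Prpf31 in CD8) in the other cell types. Of 100 groupings in which 1 library of each cell type took the role of DMSO, the real one included, 9 gave as many genes, so chance cannot be excluded for the count; the real value was 28 and the highest other 510. A drawn grouping may keep the Treg DMSO library in its role, and against that library 1401 genes were called within Treg. The groupings are thus not free of the real comparison and give no rate for chance alone. Which library gave the high counts was not examined.

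A library far from the other 5 of its cell type was found in 6 of 76 groups tested, where chance gives about 1 in 20. Penk was highest in Th17 with DMSO at 36.7 CPM (next 18.7). In Th1 Penk was lowest with WMS-83 at 777 CPM (next 911). Oprl1, the nociceptin receptor gene, was highest in Treg with DMSO at 0.738 CPM (next 0.275). The number of genes detected was highest in CD8 with WMS-200 at 24176 (next 22628). Markers of NK and gamma delta cells were highest in the same CD8 library at 17.0 CPM (next 14.9). Erythroid and platelet markers were highest in Th17 with WMS-200 at 1.57 CPM (next 0.653).

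The 1401 genes called between the agonists and DMSO in Treg rest on 1 DMSO library, and the WT number runs along with the treatment. Over the 2649 genes called without WMS-200, that library, which has the number of DMSO, lay at a median share of 0.441 of the distance from DMSO to the other 4 agonists (quartiles 0.199 and 0.669), so the number and the agonists cannot be told apart. A gene length trend does not account for the whole: with length offsets 834 of the genes were still called, while 567 were not, their median change going from 0.53 to 0.40 against a typical standard error of 0.157, and the trend stays open for those. A library standing apart stays open too: with DMSO left out WMS-200 against the other 4 agonists gave 1237 genes, 355 of them among the 1401, while WMS-64, WMS-75, WMS-76 and WMS-83 each gave 0 in that role, also with WMS-200 left out, and with 1 DMSO library a fault of that library cannot be tested. An effect of the agonists on Treg, which the design names, stays open as well.

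For the cell types, groupings of 6 libraries against the rest, with the compound as the only other term, gave as many genes as the real one in 3 of 100 for Th1 (924 genes), 2 for Th17 (3427), 1 for Treg (11353) and 3 for CD8 (1202), the real one included, and the highest other was 6528. These 4 counts come from a simpler fit than the cell type counts given above. The drawn groupings mix cell types that differ, so they do not show what libraries without differences would give. They therefore cannot decide whether chance is a source of these 4 counts. A grouping with several times the Th1 or CD8 count points to the structure of the samples, in which the other cell types also differ. Where the real count is 0 every grouping gives as many, so the groupings say nothing about chance, and only the highest other count is of use. This was so in 100 of 100 groupings for the agonists against DMSO and for the F-test (highest other 1 in both), and in 35 of 35 for each compound against DMSO, where the highest other was 10 for WMS-200, 1 for WMS-76 and 0 for the other 3. It was so in 35 of 35 for the 9 pairs of compounds with 0 genes, where the highest other was 1 for WMS-200 with WMS-64 or WMS-75, for WMS-83 with WMS-64, WMS-75 or WMS-76 and for WMS-75 with WMS-76, and 0 for WMS-200 with WMS-83 and WMS-64 with WMS-75 or WMS-76. For WMS-200 against WMS-76, 2 of 35 groupings gave 1 gene, the real one included, so chance cannot be excluded; the highest other was 1.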

How the results depend on the processing

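Fits without the Treg libraries, on 1 cell type alone and with gene length offsets were chosen after the data were seen; the other alternatives were planned. The cause of each difference was not tested, except where another threshold makes it plain. Each cell type count stayed within 1.5 times of its value under every alternative run, apart from the threshold of an absolute log2 fold change of at least 1, which by its construction left 1992, 2372, 6278 and 1997 genes for Th1, Th17, Treg and CD8. Of 51941 values of named genes under alternatives, 51358 kept their side of the threshold without a reversal, 399 lost their call, 177 gained one and 7 reversed. A change of sign was counted as a reversal only for a gene called in the reported fit or under the alternative. Signs of genes called in neither were not compared, and tests without a direction have no sign. All 7 reversals came with length offsets against the mean of the other cell types. In CD8, mt-Nd3 went from 0.44 to −0.0467 and Tnfrsf4 from 0.0119 to −0.29; in Th1, Tigit went from 0.29 to −0.13. In Treg, Nkg7 went from −0.35 to 0.66, Tnf from −0.28 to 0.31, Fasl from −0.15 to 0.33 and Klrd1 from −0.33 to 0.46. The cause was not tested.

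Without the filter on low counts there were 26 genes for the agonists, 7 for WMS-200, 46 for WMS-64, 23 for WMS-75, 27 for WMS-76, 43 for WMS-83 and 149 for the F-test. The pairs then gave 31 for WMS-200 and WMS-64, 36 for WMS-200 and WMS-75, 17 for WMS-200 and WMS-76, 36 for WMS-200 and WMS-83, 80 for WMS-64 and WMS-75, 10 for WMS-64 and WMS-76, 10 for WMS-64 and WMS-83, 16 for WMS-75 and WMS-76, 72 for WMS-75 and WMS-83 and 9 for WMS-76 and WMS-83. Within cell types it gave 5 for Th1 and 12 for Th17, 6 of them shared with the 6 reported, and 811 for the test between cell types. Limma-voom gave 5 for the agonists, 5, 4, 3 and 3 for WMS-64, WMS-75, WMS-76 and WMS-83, 3 for the F-test, 3 for WMS-200 and WMS-64, 1 for WMS-200 and WMS-75, 1 for WMS-200 and WMS-83, 1 for WMS-64 and WMS-83, and 12 for the test between cell types. DESeq2 gave 2 for the F-test, 1 for WMS-200 and WMS-75, 1 for WMS-200 and WMS-83, 5 for WMS-75 and WMS-83, 3 for Th1, 11 for Th17 and 353 for the test between cell types. DESeq2 size factors gave 1 for WMS-200 and WMS-83 and 12 for the test between cell types. The cause was not tested.

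With fewer samples, the Th1 and CD8 libraries alone, the counts were 3 for WMS-75, 1 for WMS-76, 1 for WMS-83, 24 for the F-test, 1 for WMS-200 and WMS-75, 0 for WMS-200 and WMS-76, 6 for WMS-200 and WMS-83, 1 for WMS-64 and WMS-76 and 28 for WMS-64 and WMS-83. The WT number as a block gave 0 for WMS-200 and WMS-76, 1 for WMS-64 and WMS-75 and 21 for the agonists in Treg. In Treg that block left WMS-200 against DMSO, 1 library each, in place of the 5 agonists. Without the Treg libraries there were 0 for WMS-200 and WMS-76, 21 for WMS-64 and WMS-75 and 2 for WMS-64 and WMS-83. On 1 cell type alone there were 4 for Th1, 0 for Th17 and 3 for Treg. Length offsets gave 1 for the F-test, 1 for WMS-200 and WMS-83 and 15 for the test between cell types. Of the 102 list calls by camera over all comparisons, 6 held with an estimated correlation, while fry called 113. Of the 41 camera calls for the agonists and the compounds, 4 were also called in the same direction with the block, which called 6 in all, and 2 with Th1 and CD8 alone, which called 6 in all; an estimated correlation called 0 and fry 0.

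Leaving out 1 library at a time gave 8648 to 9506 genes for Th1, 8387 to 9200 for Th17, 12425 to 12802 for Treg and 8544 to 9440 for CD8. It gave 0 to 0 for the agonists and for each compound, 0 to 2 for the F-test, 0 to 1 for WMS-200 against WMS-75, WMS-76 or WMS-83 and 0 to 0 for the other pairs. Within cell types it gave 0 to 1 for Th1, 4 to 8 for Th17, 1027 to 2649 for Treg and 1 to 1 for CD8. The test between cell types gave 10 to 1032, and the median correlation between compounds lay between 0.381 and 0.615, with 0.615 without Th1 DMSO, 0.578 without Th17 DMSO and 0.614 without CD8 DMSO, where simulated compounds without sharing gave a median of 0.586, 0.583 and 0.583. Leaving out the DMSO library of a cell type gives no value within that cell type. Depth limits genes near 0 counts, as the opioid receptor genes, where 3 counts are 0.136 to 0.192 CPM.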

Other observations

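All tests of this part were chosen after the result was seen, except that for reads shared with pseudogene copies, and the genes of the first 2 paragraphs were named after their values were seen, apart from those the rule had named.

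Single genes are given here by cell type. Th17 libraries were high in the skin and mucosal homing receptors Ccr4 (2.39 ± 0.13) and Ccr8 (2.02 ± 0.08) and in Cxcr6 (1.90 ± 0.08), against the mean of the other cell types with 6 libraries each. Treg libraries were high in Klf2, a regulator of T cell trafficking (2.44 ± 0.08), and in Il7r (1.27 ± 0.06). The adenosine-producing enzymes Entpd1 (3.55 ± 0.14) and Nt5e (3.55 ± 0.06) were both high in Treg, and Nt5e was high in Th17 as well (2.65 ± 0.06). Inhibitory receptors were spread, with Lag3 high in Th1 (1.10 ± 0.07) and CD8 (1.03 ± 0.07), Havcr2 in CD8 (1.88 ± 0.15) and Pdcd1 in Th17 (1.34 ± 0.06), and with Tigit low in Th17 (−2.62 ± 0.09).

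The list of 21 G protein and cAMP genes was not called by camera in any cell type (adjusted p = 0.294 to 0.930), and the single genes that follow do not stand for it. Rgs2, a brake on G protein signalling, was high in CD8 (2.67 ± 0.07) and Th1 (2.48 ± 0.07) and low in Th17 (−3.10 ± 0.10) and Treg (−2.05 ± 0.09). Pde4a, which degrades cAMP, was high in Treg (5.50 ± 0.12) and low in Th1 (−3.02 ± 0.19) and CD8 (−2.10 ± 0.18), while Pde4b was high in CD8 (0.79 ± 0.06) and Th1 (0.40 ± 0.06). Ramp3, a partner of receptors for calcitonin-like peptides, was high in Th1 (4.00 ± 0.12) and CD8 (2.96 ± 0.12).

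Ribosomal protein genes were low in Treg: 87 of 92 were called lower and 4 higher than in the other cell types, with a median log2 fold change of −2.69 (SD 0.93), and −2.68 with DESeq2 size factors. A trend with gene length is argued against as the whole cause, since the median stayed at −2.09 with gene length offsets. Before the offsets the median of −2.69 lay below the lowest of 10000 lists matched on gene length and expression (−1.51). The length used is that of the gene (median 1835 for these genes) and not of the transcript, so loss of short transcripts stays open. Reads shared with pseudogene copies may contribute: the 239 parents of named pseudogenes outside the ribosomal proteins had a median of −0.85, at percentile 0 of 10000 matched lists (median −0.40, lowest −0.66). A difference between the cell types stays open and was not tested. A difference in library preparation for Treg, of which the labels give no record, stays open as well, for these genes and for the 12779 genes called in Treg, and was not tested.

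Cd8a and Cd8b1 were read in the Th17 libraries, with 84.0 ± 26.9 CPM of Cd8a (33.9 to 111, n = 6), or 21.6% of the CD8 level, and 16.0% of the CD8 level of Cd8b1. For Cd8a, reads carried over alike into all libraries are argued against, since the highest Th1 or Treg library had 14.6 CPM. Cd8b1 was at 22.2 ± 2.03 CPM in Th1, or 9.19% of the CD8 level, at 6.02 ± 1.71 in Treg and at 38.6 ± 10.5 in Th17. Carry-over thus stays open for Cd8b1, and for both genes where it reached some libraries only. CD8 T cells in the Th17 cultures may be a source: Cd8b1 per Cd8a was 0.478 ± 0.087 in Th17 and 0.622 ± 0.030 in CD8, a test that leaves this open. Expression by the Th17 cells themselves stays open and was not tested.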
